A study of Homo sapiens with 6 samples.

How the data were processed

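The data are bulk RNA-seq gene counts of MCF-7 cells, a human breast cancer line positive for the estrogen receptor, that had been made resistant to palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. Per the labels, 3 libraries came from resistant control cells (PR_control) and 3 from resistant cells given a small interfering RNA against PDGFB (siPDGFB). Per the labels' protocols, RNA was purified with an RNeasy kit and made into stranded poly(A) libraries with Illumina's TruSeq kit. The groups and library numbers were taken from the labels. The labels name palbociclib as the treatment of the controls and the small interfering RNA as that of the knockdown cells. Whether both groups were kept in the drug, the sequence of the small interfering RNA and whether the controls had a non-targeting one are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

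The deposited values are raw counts per gene, with no normalization, per the file headers. The column layout is that of featureCounts, but the aligner, the counter, its strand setting and the annotation release are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The deposited count tables hold human Ensembl identifiers: 55333 of the 57447 that are also in GENCODE v29 (GRCh38), or 96.3%, have the same chromosome, start and end there. Coordinates are therefore given on GRCh38. Each table has 58143 rows, of which 92 are ERCC spike-ins, synthetic RNAs added to each sample, and 58051 are genes. The matching annotation supplied gene types, GC content and 3′ UTRs. The spike-ins took 2.11% to 3.24% of the counts and stayed out of library sizes and tests. Symbols came from a deposited table of the whole series, which names 57565 of the genes. Its 6 columns of counts were not used because their names match no sample label.

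From the counts, genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), scaled with TMM factors and tested with edgeR's quasi-likelihood F test of siPDGFB against PR_control over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p below is from this test unless another is named. The filter kept 17760 genes and removed 16227 others that had at least 1 count. Levels are given as CPM, counts scaled to library size, on TMM-scaled library sizes, as mean ± SD of 3 libraries. The error of a log2 fold change is its standard error, the size of the fold change divided by the square root of F. Of the 34 gene lists fixed before the data were examined, each was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. The camera test with an estimated correlation and the rotation test fry were alternatives.

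The genes named were set by a rule fixed at the same time. They are PDGFB and 13 other genes of its pathway and of the cell cycle, and the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among genes with a symbol other than a clone name, a mean CPM of at least 5, an adjusted p under 0.05 and no overlap between the groups. They also include up to 4 members per list with the smallest p and the 3 most abundant changed genes in each direction. Other genes are said to be chosen after their values were seen.

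Other normalizations, DESeq2 1.42.0, limma-voom, other filters, a block on library number, offsets for GC content and length, and leaving out each library were alternatives. Scaling to the spike-ins was added after the data were seen. So was testing only genes whose annotated 3′ UTR, of at least 50 bases, lacks a short sequence described with the other observations. GC content was known for 99.6% of tested genes. For 12506 genes, the log2 fold change from the fit with GC and length offsets was regressed on the presence of each 7-base word in the longest annotated 3′ UTR of at least 50 bases, with UTR length, GC content, gene length and expression as covariates. Words in fewer than 100 genes were left out.

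The test was tried on simulated counts for the same 17760 genes with 200 changed genes. It recovered 52% of those changed 1.5-fold and 92% of those changed 2-fold, and called 0.052% of the other genes. A simulated GC trend gave 2563 calls without the offsets and 0 with them. That trend was the same in all siPDGFB libraries. Simulated genes were drawn independently and no simulated library stood apart from its group, so these rates need not hold where 1 does. The search for short sequence words recovered the 1 planted in shuffled fold changes of the 12506 genes. Total counts per library were between 48202025 and 54293427. The biological coefficient of variation over genes was 11.7%, so the spread between libraries and not counting error limits the precision for all but the lowest genes. Reads of paralogs, pseudogenes and overlapping genes could have been split or lost in the authors' counting. Because the strand setting is not given, genes that overlap on opposite strands may share reads.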

Results

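Gene expression was compared between palbociclib-resistant MCF-7 cells (PR_control) and the same resistant cells with PDGFB knocked down by a small interfering RNA (siPDGFB), 3 libraries each. PDGFB encodes the B chain of platelet-derived growth factor, which signals through receptor tyrosine kinases to PI3K and AKT. The series was set up to ask how a pathway from the transcription factor RUNX1 through PDGF-BB to AKT relates to resistance against CDK4/6 inhibitors in hormone receptor-positive breast cancer. Total counts were 52767114, 48202025 and 53074969 in PR_control 1, 2 and 3 and 51939408, 54293427 and 50234455 in siPDGFB 1, 2 and 3. Between 26074 and 27133 genes had at least 1 count in a library.

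PDGFB (ENSG00000100311, minus strand of chromosome 22, 39223359 to 39244751, GRCh38) was lower in each of the 3 siPDGFB libraries than in any control. Its level was 62.4, 63.9 and 56.5 CPM in the controls and 19.03, 31.8 and 27.2 CPM in the siPDGFB libraries, from raw counts of 3194 to 3462 and of 935 to 1508. The mean fell from 60.9 ± 3.9 to 26.0 ± 6.4 CPM (SD, n = 3 each), which is 42.6% of the control level. The log2 fold change was −1.23 ± 0.17 (SE; adjusted p = 0.0017). A two-sided exact permutation test of the 6 CPM values gave p = 0.1, the smallest that 10 splits allow.

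**Figure D1:**
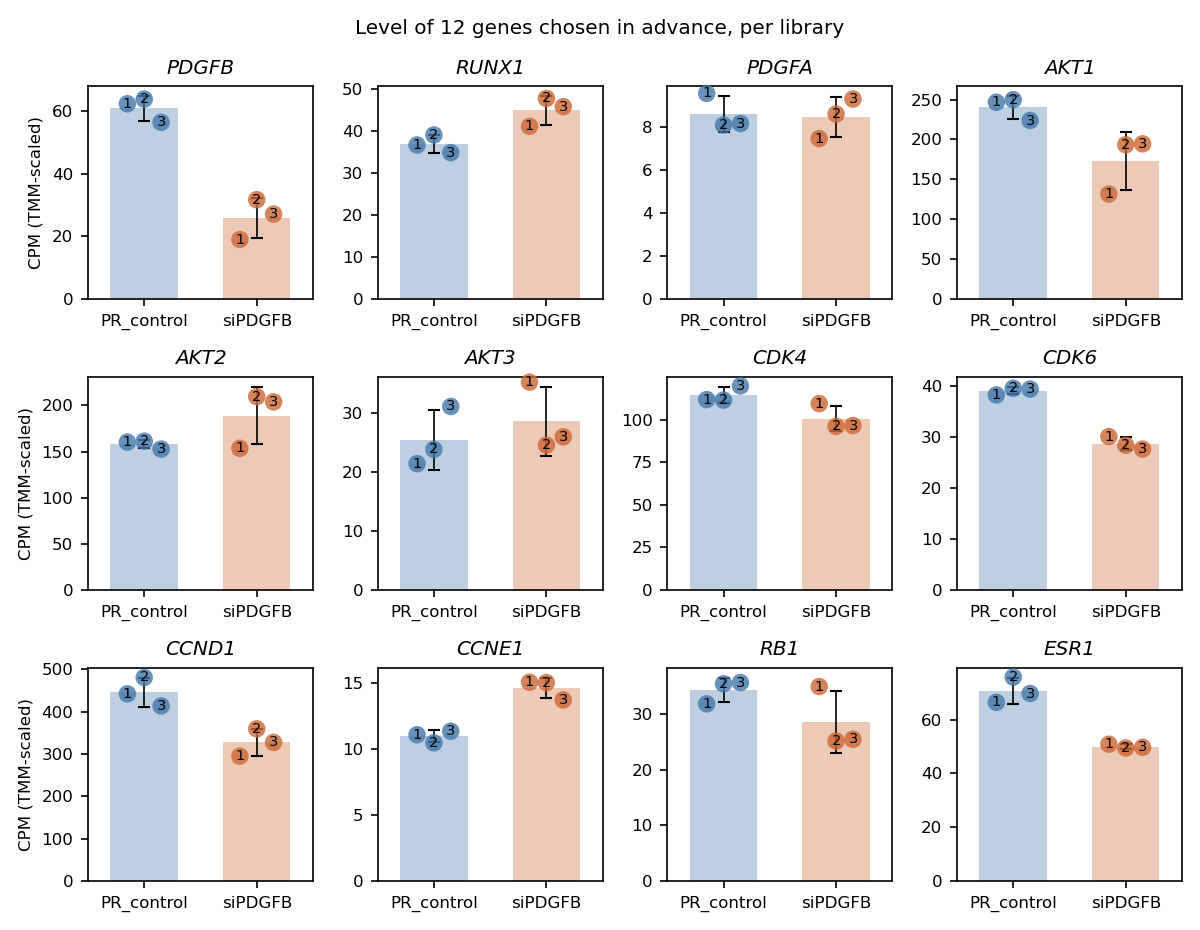
Level of 12 genes fixed in advance in each library, in TMM-scaled CPM on axes that start at 0. Numbered points are libraries, bars are means of 3 and error bars are SD. PDGFB lies between 56.5 and 63.9 CPM in PR_control and between 19.03 and 31.8 CPM in siPDGFB, and siPDGFB 1 lies below the other siPDGFB libraries for AKT1 and AKT2.

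Among the genes with the largest increases were ADM (adrenomedullin, a secreted peptide induced by hypoxia), from 52.5 ± 2.2 to 145 ± 24 CPM, and DDIT3 (the stress transcription factor CHOP), from 15.4 ± 1.1 to 38.5 ± 3.0 CPM. Their log2 fold changes were 1.47 ± 0.13 (adjusted p = 0.00055) and 1.32 ± 0.10 (adjusted p = 0.00045). GADD45G, CSRNP1, CYP1A1, CLK1, GOLGA4, PHLDA2, KCTD7, POFUT2, MAP3K14 and the histone gene HIST1H2AC completed the 12 with the largest increases, with log2 fold changes of 1.19 to 1.31. The largest decreases were in CLEC3A, a C-type lectin that fell from 34.6 ± 5.2 to 11.02 ± 0.65 CPM (log2 fold change −1.65 ± 0.12, adjusted p = 0.00045), and SLC35C1, the GDP-fucose transporter of the Golgi, with −1.61 ± 0.17 (adjusted p = 0.00091). ZNF253, ZCCHC24, IGSF5, FRAT1, ZNF468, DRAM1, ZNF189, ZNF28, FAM111B and S1PR3 followed, with log2 fold changes of −1.52 to −1.35. Among these 12 are 4 ZNF-named genes. ZNF468 and ZNF28 overlap on the same strand, KCTD7 overlaps the more abundant RABGEF1 (chosen after its values were seen; 33.3 against 21.4 CPM, log2 fold change 0.19, adjusted p = 0.26) on the same strand, and DDIT3 and MAP3K14 overlap a tested gene on the opposite strand, so reads could be shared. The annotated 3′ UTRs of 8 of the 12 genes with the largest decreases, and of 0 of the 12 with the largest increases, hold the 7-base word AAATTCA or AATTCAA, which 28.8% of 12506 expressed genes with a searched 3′ UTR hold. These words were picked on the same fold changes, as described with the other observations. The contrast therefore follows in part from that choice and is not separate support.

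Across the transcriptome, 4995 of 17760 tested genes (28.1%) passed the threshold, 2502 higher and 2493 lower in siPDGFB. Changes were mostly small, with a median absolute log2 fold change of 0.55, and 164 genes were higher and 368 lower by at least 2-fold. The 2-fold counts were 69 and 879 with library size alone, 33 and 1946 with spike-in scaling, and 292 and 574 without siPDGFB 1. The 3 libraries of each group did not overlap for 8015 genes (45.1%), where chance gives 10%. The first 2 principal components held 53.2% and 25.1% of the variance, and siPDGFB 1 stood apart from the other siPDGFB libraries on the second. Without siPDGFB 1, 9568 genes passed, and without PR_control 1, 2 or 3, 2608, 1950 or 2426 did. Without siPDGFB 3, 3006 passed. These directions are relative to the average gene: the median log2 fold change of all genes was 0.01 with TMM factors, −0.23 with library size alone and −0.44 when scaled to the spike-ins. The share of changed genes that were higher was 50.1% with TMM factors, 39.3% with upper quartile factors, 12.8% with library size alone and 1.40% with spike-in scaling. Among genes named in the paragraphs up to and including that on markers of cell types, spike-in scaling ended the calls of RUNX1, CCNE1, TSC1, KLF6, P4HA1, HMGCS1, IDI1, MVK, SQLE, FASN, ATF4, ASNS, CALR, HSPA5, TNFRSF10B, BAX, BCL2L2, RPL37, RPL32, MT-ND4, MT-CYB, NDUFA4, GAPDH, EEF1A1, EEF2, CYR61 and IRF7, all higher with TMM factors (adjusted p 0.057 to 0.93). Library size alone ended those of RUNX1, CCNE1, FASN, HSPA5, EEF2 and IRF7 (adjusted p 0.051 to 0.76). A block on library number ended those of RUNX1, AKT1, EEF2, KRT8, HNRNPA2B1 and FBN1 (adjusted p 0.056 to 0.094).

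**Figure D2:**
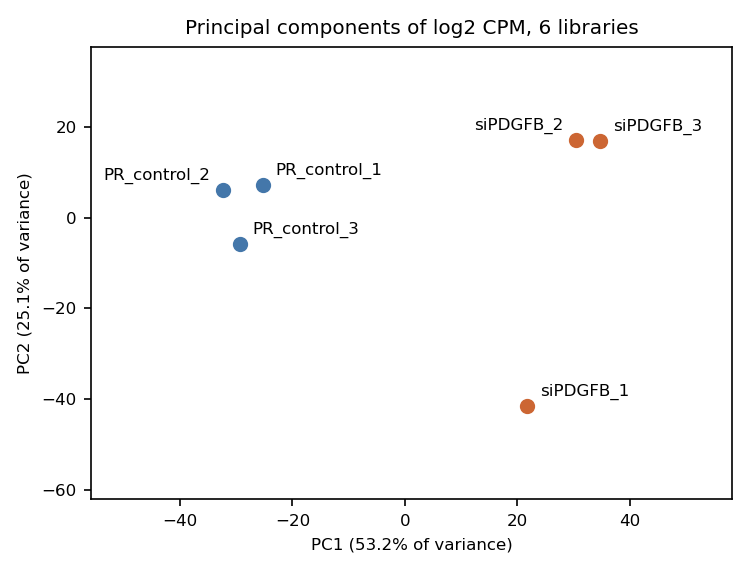
First 2 principal components of log2 CPM for the 6 libraries, coloured by group, with the percent of variance on each axis. PC1 (53.2%) separates PR_control from siPDGFB, and PC2 (25.1%) separates siPDGFB 1 from siPDGFB 2 and 3.

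For the pathway the series was set up around, several members differed between the groups by modest amounts. AKT1 fell from 240 ± 14 to 173 ± 36 CPM (log2 fold change −0.47 ± 0.15, adjusted p = 0.040), CDK6 fell from 39.1 ± 0.7 to 28.7 ± 1.3 CPM (−0.44 ± 0.08, adjusted p = 0.0055) and CCND1, which encodes cyclin D1, fell from 446 ± 34 to 327 ± 32 CPM (−0.44 ± 0.10, adjusted p = 0.013). ESR1, the estrogen receptor gene, fell from 70.7 ± 4.8 to 50.03 ± 0.76 CPM (−0.50 ± 0.09, adjusted p = 0.0038). CCNE1, which encodes cyclin E1, rose from 10.96 ± 0.45 to 14.6 ± 0.8 CPM (0.41 ± 0.09, adjusted p = 0.012) and RUNX1 from 36.9 ± 2.1 to 44.9 ± 3.4 CPM (0.28 ± 0.09, adjusted p = 0.049), although under spike-in scaling their log2 fold changes were −0.04 and −0.16, short of the threshold. The RUNX1 call was lost or reversed under 12 of 18 alternatives, among them limma-voom (adjusted p = 0.051) and leaving out any library but siPDGFB 1 (adjusted p 0.11 to 0.19). The AKT1 call was lost without any 1 of the 3 controls (adjusted p 0.082 to 0.14), and the CCND1 and CCNE1 calls without PR_control 1 or 2 (adjusted p 0.053 to 0.079). The 3′ UTRs of CDK6 and CCND1 hold the word AAATTCA and that of RUNX1 holds AATTCAA. Those of AKT2 and AKT3, which were not lower (log2 fold changes 0.26 and 0.17), also hold AAATTCA. Those of AKT1, ESR1 and CCNE1 hold neither word.

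PDGFA (−0.03 ± 0.12, adjusted p = 0.89), AKT2 (0.26 ± 0.12, adjusted p = 0.14), AKT3 (0.17 ± 0.17, adjusted p = 0.50), CDK4 (−0.18 ± 0.09, adjusted p = 0.15) and RB1 (−0.27 ± 0.13, adjusted p = 0.17) did not pass. Without siPDGFB 1, AKT2 (0.37), CDK4 (−0.26) and RB1 (−0.45) did pass. So did AKT2 and RB1 with GC and length offsets (adjusted p = 0.029 and 0.021), CDK4 and RB1 with library size alone (0.016 and 0.042) and RB1 with spike-in scaling (0.028). The receptor genes PDGFRA and PDGFRB had 7 to 16 and 3 to 9 counts per library, too few to test. Of 25 components of the PI3K-AKT-mTOR pathway, 3 rose and 5 fell (4 and 6 adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.90). TSC1, a brake on mTOR, rose (0.62 ± 0.09, adjusted p = 0.0018) and PIK3R1, a regulatory subunit of PI3K, fell (−0.50 ± 0.12, adjusted p = 0.014; 0.051 to 0.070 without PR_control 2, PR_control 3 or siPDGFB 3). Targets of FOXO factors, which AKT restrains, split as 4 higher and 4 lower of 20 (5 and 4 adjusted over the list alone; camera adjusted p = 0.59), with KLF6 higher (0.78) and SESN3 lower (−1.12). Under spike-in scaling 0 FOXO targets rose and 4 fell, with a median of −0.37 against 0.09 with TMM factors. The 5 tested PDGF ligand and receptor genes (1 rose, 1 fell; 1 and 2 adjusted over the list alone) and the 6 RUNX and CBFB factors (2 rose; also 2 adjusted over the list alone) did not pass as lists either, at camera adjusted p = 0.85 and 0.60.

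Genes of cell division were lower. Of 28 mitosis genes, 25 fell and 0 rose (27 fell adjusted over the list alone), with a median log2 fold change of −0.55 and camera adjusted p = 3.62e-11 (adjusted p = 0.33 with an estimated correlation). KIF20A, a mitotic kinesin, fell by 1.03 on the log2 scale (SE 0.09, adjusted p = 0.00055), CENPA, the centromeric histone H3, fell by 0.81 (SE 0.10), the mitotic kinase gene AURKA by 0.77 (SE 0.10) and cyclin B1 (CCNB1) by 0.73 (SE 0.08). Of 31 E2F target and DNA replication genes, 16 fell and 1, CCNE1, rose (18 and 1 adjusted over the list alone; median −0.34, camera adjusted p = 1.07e-05; adjusted p = 0.33 with an estimated correlation), including CCNA2, TYMS, UHRF1 and PCNA at −0.87, −0.63, −0.71 and −0.47. Without siPDGFB 1, all 28 mitosis genes and 27 of the E2F genes fell. Among members whose 3′ UTR lacks the 6-base word AATTCA, 16 of 19 mitosis genes and 11 of 25 E2F genes fell. The 18 G1 cyclins, kinases and inhibitors held 1 gene that rose and 4 that fell (also 1 and 4 adjusted over the list alone; camera adjusted p = 0.13), among them the inhibitor gene CDKN2C (−0.68 ± 0.08, adjusted p = 0.0012).

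The estrogen receptor and its targets were lower as a list, with 9 of 25 falling and 1 rising (13 and 2 adjusted over the list alone; median −0.37, camera adjusted p = 0.024; adjusted p = 0.40 with an estimated correlation). OLFM1, RAB31 and the chemokine gene CXCL12 fell by 0.88, 0.76 and 1.27 on the log2 scale. The list's call was lost without siPDGFB 1 (adjusted p = 0.13). It was also lost when only genes with a searched 3′ UTR that lacks the word AATTCA were tested (camera adjusted p = 0.23). That also left out genes without a searched 3′ UTR.

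Replication-dependent histone genes went the other way from the mitosis genes, with 8 of 12 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 0.0014; adjusted p = 0.35 with an estimated correlation). Under spike-in scaling 2 rose and 2 fell, with a median of 0.17. HIST1H2AC and HIST2H2BE rose by log2 fold changes of 1.19 ± 0.10 and 1.18 ± 0.12. Most histone mRNAs lack a poly(A) tail, and members of this family share sequence, so counts from poly(A) libraries are uncertain for them.

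Hypoxia and glycolysis genes were higher. Of 24 tested, 19 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 fold change of 0.65 (camera adjusted p = 1.85e-09; adjusted p = 0.33 with an estimated correlation). The hexokinase gene HK2 rose from 671 ± 16 to 1489 ± 137 CPM (1.15 ± 0.10, adjusted p = 0.00055), VEGFA from 114 ± 4 to 250 ± 27 CPM (1.13 ± 0.10, adjusted p = 0.00055) and the collagen prolyl hydroxylase gene P4HA1 from 172 ± 13 to 315 ± 39 CPM (0.87 ± 0.11, adjusted p = 0.0013). Without siPDGFB 1, 24 of 24 rose. Under spike-in scaling 3 rose and the median was 0.19. Cholesterol synthesis genes were higher too, with 15 of 21 rising and 0 falling (18 adjusted over the list alone; median 0.51, camera adjusted p = 1.58e-07; adjusted p = 0.33 with an estimated correlation), with 9 rising under library size alone, and 0 rising, 1 falling and a median of 0.05 under spike-in scaling. Among them were HMGCS1 (1.13 ± 0.13), IDI1 (0.96 ± 0.11), MVK (0.79 ± 0.10) and SQLE (0.76 ± 0.09). The 12 fatty acid synthesis genes split as 3 higher and 3 lower (also 3 and 3 adjusted over the list alone; camera adjusted p = 0.97), with FASN higher (0.52 ± 0.15; adjusted p = 0.028, and 0.086 to 0.10 without any library but siPDGFB 1) and FADS2 lower (−0.49 ± 0.09). The mean of that list was 0.05 and its median −0.05. FADS2 overlaps the more abundant FEN1 (chosen after its values were seen) on the same strand, so reads could be shared. FEN1 had 64.4 CPM against 13.3 and was also lower (log2 fold change −0.43, adjusted p = 0.0057).

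Targets of ATF4, the transcription factor of the amino acid and integrated stress response, rose in 13 of 19 cases and fell in 1 (15 and 1 adjusted over the list alone), with a median of 0.43, or −0.02 under spike-in scaling, where 2 rose and 1 fell (camera adjusted p = 3.45e-06; adjusted p = 0.33 with an estimated correlation). ATF4 itself went from 198 ± 13 to 388 ± 47 CPM (0.97 ± 0.11, adjusted p = 0.0010) and ASNS, asparagine synthetase, from 49.4 ± 2.9 to 97.4 ± 9.9 CPM (0.98 ± 0.10, adjusted p = 0.00081). Of 16 ER chaperone genes of the unfolded protein response, 5 rose and 1 fell (also 5 and 1 adjusted over the list alone), with a median of 0.18, or −0.06 with library size alone and −0.28 under spike-in scaling (camera adjusted p = 0.030; adjusted p = 0.33 with an estimated correlation). CALR and HSPA5 rose by 0.62 ± 0.08 and 0.57 ± 0.11, and SDF2L1 fell by 0.48 on the log2 scale (SE 0.12; its call was lost without PR_control 2 or 3, adjusted p = 0.084 and 0.078). The ER chaperone call was lost with library size alone (camera adjusted p = 0.18, where 1 rose and 2 fell). It was also lost under spike-in scaling (adjusted p = 0.15, where 0 rose and 1 fell) and without siPDGFB 1 (adjusted p = 0.084). Testing only genes with a searched 3′ UTR that lacks AATTCA ended it too (adjusted p = 0.28), although the median of its 10 members there was 0.19. Of 24 p53 target genes, 11 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.31, or −0.14 under spike-in scaling (camera adjusted p = 0.0073; adjusted p = 0.33 with an estimated correlation). Under spike-in scaling 0 rose, 4 fell and the list's call was lost (adjusted p = 0.072). The death receptor gene TNFRSF10B and the apoptosis gene BAX rose (0.63 ± 0.08 and 0.55 ± 0.09), while FAS, another death receptor gene, fell (−0.91 ± 0.14). The BCL2 family (4 rose and 1 fell of 15; 5 and 1 adjusted over the list alone; camera adjusted p = 0.17) and heat shock genes (1 rose and 1 fell of 15; 0 and 1 adjusted over the list alone; camera adjusted p = 0.97) did not pass as lists. In the BCL2 family 2 rose and 2 fell with library size alone, and 0 rose and 3 fell under spike-in scaling. BCL2L2 rose from 30.4 ± 2.8 to 60.99 ± 8.56 CPM and HSPH1 fell by 0.72 on the log2 scale (SE 0.11).

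Transcripts of the translation and respiratory machinery were higher with TMM factors. Of 30 cytosolic ribosomal protein genes, 21 rose and 0 fell (27 adjusted over the list alone), with a median of 0.42, or −0.04 under spike-in scaling (camera adjusted p = 3.02e-08; adjusted p = 0.43 with an estimated correlation). With library size alone 5 rose, and under spike-in scaling 0 did. RPL37 and RPL32 rose by 0.52 ± 0.08 and 0.66 ± 0.14. All 13 mitochondrially encoded genes rose (13 adjusted over the list alone), with a median of 0.51, but 5 passed with library size alone and 0 under spike-in scaling, where the median was 0.05 (camera adjusted p = 1.33e-06; adjusted p = 0.40 with an estimated correlation), for example MT-ND4 (0.69 ± 0.10) and MT-CYB (0.65 ± 0.10). The mitochondrial chromosome took 2.39 ± 0.13% of gene counts in PR_control and 3.11 ± 0.41% in siPDGFB, with the highest share, 3.57%, in siPDGFB 1. Of 25 nuclear oxidative phosphorylation genes, 10 rose and 0 fell (11 adjusted over the list alone), with a median of 0.22, or −0.01 with library size alone and −0.24 under spike-in scaling (camera adjusted p = 0.00018; adjusted p = 0.40 with an estimated correlation). With library size alone 2 rose, and under spike-in scaling 0 did. NDUFA4, a cytochrome c oxidase subunit, rose by 0.66 ± 0.10 (adjusted p = 0.0026). The most abundant genes that rose were GAPDH (0.81 ± 0.18), EEF1A1 (0.62 ± 0.10) and EEF2 (0.59 ± 0.15), and those that fell were KRT8 (−0.46 ± 0.14), HNRNPA2B1 (−0.41 ± 0.11) and EIF5A (−0.66 ± 0.12). Under spike-in scaling the log2 fold changes of GAPDH, EEF1A1 and EEF2 were 0.36, 0.16 and 0.14, short of the threshold. The calls of EEF2, KRT8 and HNRNPA2B1 were lost without any 1 of the controls (adjusted p 0.068 to 0.12) or without siPDGFB 3 (0.052 to 0.096). Those of EEF2 and HNRNPA2B1 were also lost without siPDGFB 2 (0.065 and 0.080), and that of GAPDH without PR_control 2 or 3 (0.059 and 0.051). Many of these have processed pseudogenes, and KRT8 and HNRNPA2B1 overlap a gene on the opposite strand. The 10 most abundant genes took 7.31% to 7.84% of gene counts in PR_control and 8.92% to 10.5% in siPDGFB.

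**Figure D3:**
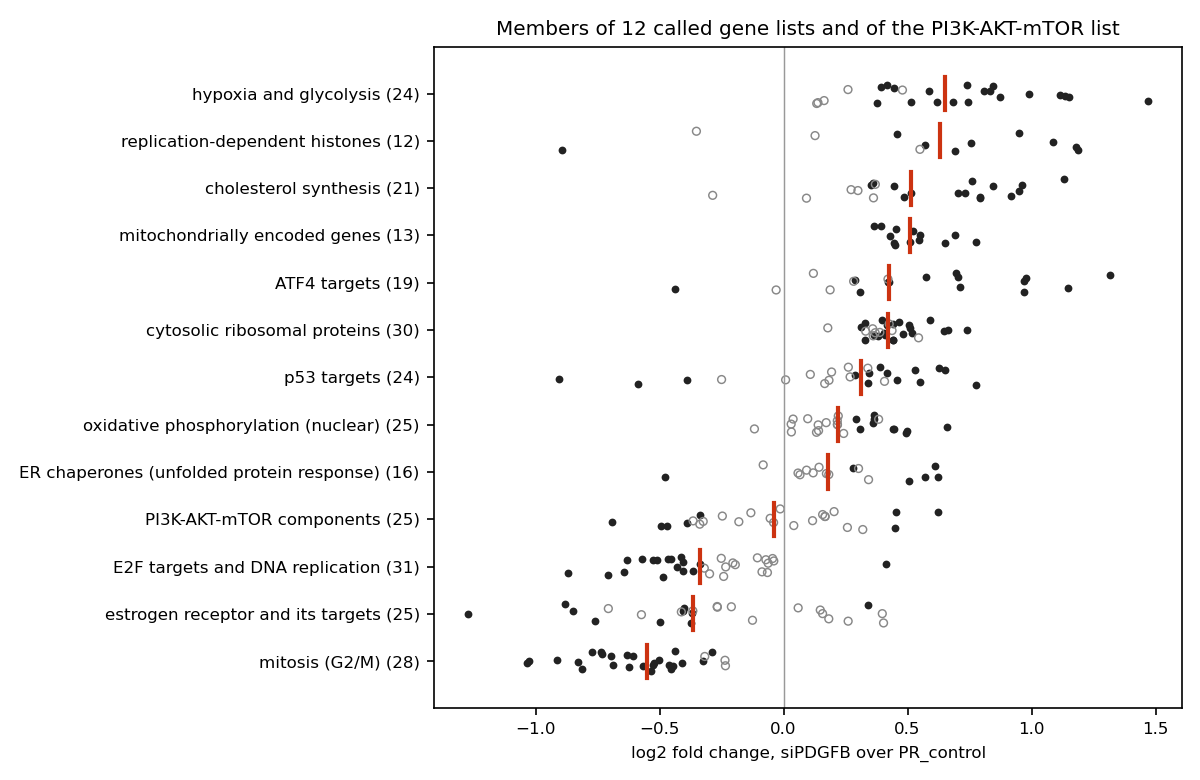
Log2 fold change (siPDGFB over PR_control, TMM-scaled) of each tested member of the 12 gene lists that passed the camera test at the preset correlation, and of the PI3K-AKT-mTOR list, with the number of members in parentheses. Filled points passed the threshold, open points did not, and red lines are medians. Medians run from −0.55 for mitosis to 0.65 for hypoxia and glycolysis. Under spike-in scaling those of the p53, ATF4, ER chaperone, oxidative phosphorylation and ribosomal protein lists lie below 0.

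The remaining lists did not pass. Of 28 interferon-stimulated genes, 3 rose and 6 fell (also 3 and 6 adjusted over the list alone; camera adjusted p = 0.28), with OAS3 lower (−0.99 ± 0.12, adjusted p = 0.0012) and IRF7 higher (0.87 ± 0.24, adjusted p = 0.026, and 0.073 to 0.10 without any library but siPDGFB 1). Immediate early genes and ERK targets had 7 higher and 2 lower of 24 (10 and 3 adjusted over the list alone; camera adjusted p = 0.15), led by ATF3 (1.15 ± 0.14) and CYR61 (0.88 ± 0.11). Of these 24, 3 rose and 6 fell with library size alone, and 1 rose and 5 fell under spike-in scaling. Of 23 receptor tyrosine kinase genes, 1 rose and 7 fell (also 1 and 7 adjusted over the list alone; camera adjusted p = 0.057, 0.019 with library size alone, and 0.025 to 0.048 without PR_control 1, siPDGFB 2 or siPDGFB 3), with FGFR3 (−0.82 ± 0.13), FGFR4 (−0.59 ± 0.13) and MET (−0.38 ± 0.09) lower. The FGFR4 call was lost without PR_control 2 (adjusted p = 0.054) and the MET call without any 1 of the controls or siPDGFB 3 (adjusted p 0.051 to 0.067). TGF-β pathway genes had 3 higher and 5 lower of 21, NF-κB and inflammatory genes 2 and 1 of 12, ABC drug transporters 1 and 2 of 10, and the small interfering RNA machinery 1 and 1 of 13. Adjusted over the list alone these were 3 and 5, 3 and 3, 1 and 2, and 1 and 1, with camera adjusted p of 0.97, 0.94, 0.97 and 0.97. Mesenchymal genes had 1 higher and 3 lower of 20, and epithelial genes 4 higher and 1 lower of 17 (1 and 2, and 4 and 1, adjusted over the list alone; camera adjusted p = 0.39 for each). With library size alone 0 epithelial genes rose and 3 fell, and under spike-in scaling 0 rose and 2 fell. The epithelial median was 0.11 with TMM factors, −0.13 with library size alone and −0.35 under spike-in scaling.

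Markers of mammary and other cell types were mixed. Luminal mammary markers had 1 higher and 4 lower of 12 and basal markers 1 higher and 0 lower of 7 (1 and 6, and 0 and 0, adjusted over the list alone; camera adjusted p = 0.089 and 0.63). The luminal list passed with library size alone (adjusted p = 0.048) and without PR_control 3, siPDGFB 2 or siPDGFB 3 (adjusted p 0.040 to 0.048). Of the 7 fibroblast, 4 endothelial and 3 leukocyte markers that could be tested, 2, 1 and 1 fell and 0 rose (the same counts adjusted over the list alone; camera adjusted p = 0.97, 0.54 and 0.26). The fibroblast list had a median of 0.21 and a mean of 0.11 but a downward camera direction. The endothelial list passed without siPDGFB 3 (adjusted p = 0.028). Called fibroblast markers were COL3A1 (13.6 ± 0.7 to 8.35 ± 0.53 CPM) and FBN1 (9.97 ± 1.25 to 7.15 ± 0.99 CPM), and CORO1A was the called leukocyte marker (log2 fold change −0.49 ± 0.10). The FBN1 call held only without PR_control 1 or siPDGFB 1 (adjusted p 0.095 to 0.12 without each of the others), and that of CORO1A was lost without PR_control 2 (adjusted p = 0.055).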

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

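The tests of the spike-ins in this part were chosen after the data had been seen, and the others before. The ERCC spike-ins are outside the comparison of genes, and their share of the counts was above the highest control, 2.78%, in siPDGFB 1 (3.10%) and in siPDGFB 3 (3.24%). In siPDGFB 2 it was 2.25%, within the control range of 2.11% to 2.78%, so the group means of 2.45 ± 0.33% and 2.86 ± 0.54% (SD, n = 3 each) differ by less than the larger SD. A higher share with an equal amount of spike-in would mean less other RNA per library, but the amount added is not given in the sources used here.

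Library siPDGFB 1 stood apart from siPDGFB 2 and 3, with a chi-square per degree of freedom of 95.2 and 86.0 against each over genes, where siPDGFB 2 and 3 differed by 6.02 and the controls by 6.24 to 9.72. A stronger form of the same response is argued against as the sole source: over genes, its difference from siPDGFB 2 and from siPDGFB 3 correlated negatively with the response of the remaining library (r = −0.25 and −0.30; genes are not independent replicates). These values were not corrected for GC content, so a stronger response together with a GC bias stays open. PDGFB itself was lowest in siPDGFB 1, at 19.03 CPM against 31.8 and 27.2 in siPDGFB 2 and 3. A bias of preparation or sequencing stays open and may account for part of the distance, because the spike-ins, which no cell makes, were also shifted in siPDGFB 1: their SD about its group mates was 1.67 times the largest of any other library. Its deviation from its mates followed GC content (r = −0.58 over genes), and removing each library's trend on GC content and length took away 46.5% of its excess spread, between the values set in advance for and against that trend as the main source. A difference between cultures was not tested.

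Of the breadth of the change, 4995 genes, GC content and length bias is argued against as the whole source, since 7733 genes passed with offsets for both. Technical differences that also reach the spike-ins are argued against as the whole of it: 0 of 66 tested spike-ins, or 0%, passed in edgeR (0 also at an unadjusted p under 0.05), and their median absolute log2 fold change was 0.07 against 0.28 for genes. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05: only 1, the real one, gave as many genes, and the highest of the others gave 0 in edgeR, with 62 to 1783 at an unadjusted p under 0.05. For the gene lists the real split called 12, only 1 split gave as many, and the highest of the others called 10. At the preset correlation of 0.01, splits that do not follow the groups thus also called lists. Each of those splits mixes the groups unequally and keeps part of their difference. Their calls therefore do not measure a rate without a group difference. Loss of PDGFB, transfection, effects of the small interfering RNA on other genes, and any difference in palbociclib between the groups all follow the same 3 against 3 libraries, so the counts of changed genes cannot separate them.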

How the results depend on the processing

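Spike-in scaling and the restriction to genes without a 3′ UTR match to AATTCA were chosen after seeing the data. That restriction also left out genes without a searched 3′ UTR. PDGFB kept its direction and passed under every alternative run, with log2 fold changes of −1.40 to −1.06 when each library was left out. Using the series-wide count table in place of the separate ones was not run, because its columns could not be tied to samples. The number of changed genes, 4995 (2502 higher, 2493 lower), was within 1.5 times with RLE factors (4997), upper quartile factors (4933, of which 39.3% higher against 50.1%), DESeq2 (5419), limma-voom (4901), no filter (5772), a CPM filter (4809) and protein-coding genes (4500). With library size alone 763 were higher and 5183 lower (12.8% higher), and with spike-in scaling 67 and 4710 (1.40% higher). Offsets for GC content and length gave 7733 (4121 higher). Among the 8285 genes without the match, 2553 passed, 1215 higher and 1338 lower, fewer because fewer were tested. Genes changed at least 2-fold, 164 higher and 368 lower, became 69 and 879 with library size alone, 33 and 1946 with spike-in scaling, 42 and 142 without the match, and 69 and 226 with the CPM filter, and 83 were higher among protein-coding genes. Apart from the smaller gene sets, the cause was not tested.

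A replicate block on library number gave 3207 genes (1496 higher), and 6446 with the GC and length offsets. Libraries with the same number did not deviate together (correlations −0.19, 0.11 and −0.17 over genes). Each deviation is from the mean of its own group, so those within a group tend to correlate negatively (−0.52 to −0.46 among the controls). Deviations of siPDGFB 1 ran opposite to those of siPDGFB 2 and 3 more strongly (−0.71 and −0.72) and could hide a shared effect. Whether the numbers pair libraries therefore stays open.

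Leaving out each library in turn gave 1950 to 9568 changed genes, lowest without PR_control 2 and highest without siPDGFB 1, with 895 to 4725 higher, 1055 to 4843 lower, 110 to 292 higher and 251 to 574 lower by at least 2-fold, and 10 to 15 lists called. Fewer samples can lower such counts, but the count rose without siPDGFB 1, and the cause of these differences was not tested. Of the 12 called lists, 0 passed with an estimated correlation and fry called 17 of the 34.

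Of 163 named genes, 15 of those called changed sign under spike-in scaling, none past the threshold there: RUNX1 (−0.16), CCNE1 (−0.037), CBFA2T2 (−0.10), EIF4EBP1 (−0.0058), ESRP1 (−0.13), NFKB2 (−0.021), MCL1 (−0.068), SCD (−0.0096), COX5B (−0.025), ABCC5 (−0.069), AGO1 (−0.10), RPL10A (−0.023), DNAJB1 (−0.17), EGFR (−0.058) and TFAP2A (−0.030). Another 46 lost and 9 gained a call. With library size alone 27 lost and 8 gained one, with the replicate block 24 lost one, leaving out siPDGFB 1 lost 1 and each other library 21 to 47, and 0 of the named genes called in the comparison changed sign under the other alternatives. Depth limits only the lowest genes, such as PDGFRA and PDGFRB with 3 to 16 counts per library.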

Other observations

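The ZNF-named zinc finger genes, which encode DNA-binding proteins clustered on chromosome 19, were looked at after 4 of them appeared among the largest decreases. Of 461 tested, 143 fell and 30 rose, with a median log2 fold change of −0.19 against 0.02 for all other genes. Random lists of other protein-coding genes matched on expression had a typical median of −0.08, and the lowest of 10000 was −0.16. Part of the difference may therefore go with expression level or gene type, which these lists do not separate. The median was −0.25 for the 221 on chromosome 19, −0.16 for the 240 elsewhere and −0.17 with GC and length offsets. Without siPDGFB 1, 241 fell (median −0.30). The fall went in part with a short sequence word described next: in the 199 ZNF genes whose 3′ UTR lacks AATTCA the median was −0.01 (0.06 in other genes without it) and 31 fell, and in the 41 with AAATTCAA it was −0.41. Reads of these related genes could be shared.

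The test of base composition in 3′ UTRs and the separate scalings and libraries were chosen after the association had been seen. So were the fits with covariates and the lists without the match. The test of base composition in coding sequences names the word found in 3′ UTRs, so it was set after that search but before its own result. The others were chosen before. A small interfering RNA can lower other mRNAs that match its seed, bases 2 to 8 of its guide strand, most often in the 3′ UTR. Of 15990 7-base words tested in the 3′ UTRs of 12506 genes, AAATTCA had the most negative association with the log2 fold change (z = −14.7, in 2868 genes), and AATTCAA, which shares the 6 bases AATTCA with it, the next (z = −13.6). The largest positive z was 4.29, the Bonferroni threshold was 4.66, and 15 words passed it on the negative side and 0 on the positive. AAATTCA was also first without offsets, with library size alone, and without siPDGFB 1, 2 or 3 in turn (z = −15.1 to −13.8), while between PR_control 1 and the other controls its z was −0.10. In that comparison, which holds no knockdown, other words reached z = −4.66 and 6.29, so passing the Bonferroni threshold alone does not set a word apart. It occurs once in the PDGFB mRNA, in coding exon 6 of 7 of the annotated transcripts, at 39225770 to 39225776 on chromosome 22 (minus strand, GRCh38). There it is part of the 8-base word AAATTCAA, at the end of the reference stretch GGGCAAGCACCGGAAATTCAA (39225769 to 39225789). Of all words tested, 18.6% occur in that mRNA.

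The median log2 fold change was −0.15 in 984 genes with AAATTCAA in the 3′ UTR, −0.08 in 1884 with AAATTCA only, −0.06 in 735 with AATTCAA only, −0.0026 in 1516 with AATTCA only and 0.06 in 7387 with none. This order was not in siPDGFB 1, where the medians against the control mean were −0.03, 0.04, 0.04, 0.06 and −0.03. In siPDGFB 2 and 3 the first class lay at −0.23 and the last at 0.09, and without siPDGFB 1 the first lay at −0.25 and the last at 0.07. Genes with these words have longer 3′ UTRs (medians of 3384 and 842 bases for the first and the last class). With UTR length, GC content, gene length and expression as covariates, the classes lay −0.22, −0.14, −0.13 and −0.06 from genes with none (SE 0.01 each, over genes, which are not independent replicates). With the same covariates siPDGFB 1 alone against the controls gave −0.22, −0.15, −0.13 and −0.07 (SE 0.01 to 0.02), and AAATTCA was the most negative word in each siPDGFB library (z = −14.4, −14.1 and −13.1), though the 3 comparisons share their controls. Of the first class 28.5% fell and 9.86% rose, and of the last 13.2% fell and 18.98% rose.

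The hypothesis is that part of the lower calls may come from silencing through the seed of the small interfering RNA and not from loss of PDGFB. The association of a word of the PDGFB mRNA (z = −14.7) and the order by site type, with a difference of −0.21 between the first and last class, are what it predicts. That difference carries no covariates, and with them it was −0.22. The classes were built from the word picked on these same fold changes, so lower medians in them follow in part from that choice. The order is therefore not separate support. The order did come out otherwise in the medians of siPDGFB 1 and came out as predicted there only with the covariates. Base composition of the 3′ UTRs is argued against, since the most negative of the other arrangements of the same bases without AATTCA, AAAATTC, reached 0.46 of the association. A search over coding sequences kept genes that also hold the word in the 3′ UTR, so it is not independent of the 3′ UTR search. Over that part of the mRNA AAATTCA was again the first of 16290 words (z = −10.3). There another arrangement reached 0.58 of it, which leaves composition open for that part, and genes with AAATTCAA only in the coding sequence (n = 283) lay 0.75 times as far below genes with none as those with it only in the 3′ UTR (95% bootstrap interval 0.44 to 1.12). The interval reaches on both sides of the share set in advance, the medians carry no covariates and composition is open there, so an effect of 3′ UTR sites alone stays open.

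Seed matches in the 3′ UTR are argued against as the whole of the lower calls, because 13.2% of genes with no AATTCA there were also called lower. Some of those genes hold it in the coding sequence, as 5688 genes held it in neither part. Coding matches are therefore not covered. Of 3603 genes with a match of at least 7 bases, 858 fell, where the rate in genes with none would give 477. The excess of 381 is 17.0% of 2247 lower expressed genes and takes no account of UTR length. Those 2247 include genes without a searched 3′ UTR, so the share among lower genes with one is larger. A microRNA with the same seed that changed between the groups could give the same association, and the sequence of the small interfering RNA is not given in the sources used here, so the source of the seed stays open. The restriction to genes without the match also left out genes without a searched 3′ UTR. Among genes without the match the mitosis and E2F lists passed at the preset correlation (camera adjusted p = 1.19e-07 and 8.34e-05), though with all genes neither passed at an estimated one (adjusted p = 0.33 for each). The call of the estrogen receptor list was lost (adjusted p = 0.23), with a median of −0.08 in the 12 members without the match against −0.37 in all 25, and the 7 FOXO targets without the match passed as higher at the preset correlation (adjusted p = 0.026), though the list of 20 did not pass with all genes (adjusted p = 0.59, or 0.72 at an estimated correlation). The ER chaperone call was lost too (adjusted p = 0.28) with no smaller median, 0.19 in 10 members against 0.18 in all 16.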
